A study of Homo sapiens with 12 samples.

How the data were processed

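MicroRNAs (miRNAs) were measured in human primary trabecular meshwork cells, the cells of the eye's aqueous outflow tissue, grown as 12 cultures. Per the labels, 6 cultures were held without stretch and 6 underwent 15% cyclic stretch at 1 cycle per second for 24 hours. The cultures used here come from 5 cell strains, called A to E. Strains A, B, D and E gave 1 control and 1 stretched culture each, and strain C gave 2 of each. The titles mark the cultures with C or S, read here as control and stretched. The assay, per the labels' protocols, hybridized total RNA to color-coded probes and cleaned the complexes with magnetic beads.

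The deposited values are normalized counts, which are treated here as a score because they are not raw counts: the authors' table is described as normalized, and its values are whole numbers with a floor of 1. The method of normalization is not given in the sources used here. limma is named in the submitters' processing notes, without its role. The table holds 798 probes, and a second deposited table held the same values (0 differed). In 5 of the 12 cultures at least 1 whole number from 3 to 20 did not occur. This happens when counts are multiplied by a factor above 1 and rounded. The other cultures did not show this, but the check cannot see a factor below 1. A likelihood fit to the steps among low values gave factors below 1 in some cultures. Examples are 0.785 and 0.87 in the stretched cultures of strains B and A. Because the values are described as normalized, a count test was not used. Column medians lay between 13 and 14, taken here as background, while column sums ran from 37164 to 297976. The low values were thus alike across cultures and the totals were not. The fitted factors ranged from 0.785 to 1.36, within a limited search range. They did not follow the totals. The control culture of strain A had 0.945 at a total of 297976, and 1 control culture of strain C had 1.045 at 37164. This argues against a multiplying factor as the source of the unequal totals in these cultures. Whether the scaling evened the low values is not known. No raw counts were used here, so counting error cannot be given, and precision rests on the spread between strains, which the main fit pooled over miRNAs.

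A probe was kept where its mean over the 12 cultures was at least 30, which left 163 and removed 635. Values were taken as log2(value + 1) with the background left in, so the change of a low miRNA is understated. Cultures of the same strain and condition were averaged on this scale, giving 5 control and 5 stretched strain means, and limma 3.58.1 in R 4.3.3 fitted stretch with the strain as a block (eBayes with trend, Benjamini-Hochberg adjustment, threshold 0.05). The strain pairs the conditions because the labels give it for each culture. After subtracting the group means, control and stretched means of the same strain correlated with r between 0.73 and 0.89 across miRNAs, and each control mean correlated best with its own strain. Exact permutation tests used all 96 relabellings of cultures within strains, so the smallest two-sided p is 0.0208. Errors are SD over 5 strains unless given as SE. Whether cultures of a strain were grown on separate days is not given in the sources used here.

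Before the data were examined, 24 lists were written: the miR-29, let-7, miR-30, miR-200 and miR-15/16 families; the miR-23/27/24, miR-17-92 and miR-183 clusters and the miR-221/222 pair; the imprinted DLK1-DIO3 cluster and the placental C19MC cluster; lists for smooth muscle, fibrosis, senescence, hypoxia and vascular flow; markers of blood, endothelial, epithelial, striated muscle, neuronal, liver and pluripotent cells; and housekeeping mRNAs. Lists with at least 3 kept members (10 lists) were tested with camera at its preset correlation of 0.01, with an estimated correlation and fry beside it. The miRNAs named in the text follow a rule fixed at the same time: those past the threshold that changed the same way in all 5 strains, then, since fewer than 10 qualified, those with the smallest p that changed the same way in all 5 strains, up to 20 names; up to 4 kept members of each list with the smallest p; and the 10 most abundant in control cells.

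The sums of squares of strain and stretch over the kept miRNAs gave their shares of variance. The alternatives fixed before the data were examined changed the pseudocount to 10, the filter to none or to a mean of 100, and the scaling to equal medians, an equal geometric mean of the 100 most abundant miRNAs (top-100 scaling) or quantile normalization. They also changed the block, the variance model and the list test, and left out each strain and each culture of strain C. Cultures were also parted by their total at 100000 after this split had been seen. The fit was tested on simulated data with the real strain means and residual SDs, for stretched against control strain means over 163 miRNAs, in 50 simulations. It recovered 16.8% of miRNAs changed 1.5-fold, 54.8% of those changed 2-fold and 97% of those changed 4-fold, and 1 of 50 simulations without a change gave a call. A list of 9 miRNAs moved 1.5-fold was recovered in 100% of simulations. That simulation draws independent residuals, unlike the correlated miRNAs of the real cultures. No genome was used, so no coordinates are given. Probes that name several miRNAs cannot tell them apart and keep their joint name.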

Results

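The data were normalized miRNA counts of 6 control and 6 stretched cultures of human trabecular meshwork cells from 5 strains. The comparison asks which miRNAs change under cyclic mechanical stretch. The summed signal of a culture differed 8.02-fold between the lowest and the highest. In 6 cultures the sum lay between 193011 and 297976, and in the other 6 between 37164 and 85629. These signal sets were defined from the data, not by the study, and each held 3 control and 3 stretched cultures. The high-signal set held strains A and B and 1 culture per condition of strain C, and the low-signal set held strains D and E and the others of strain C.

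**Figure D1:**
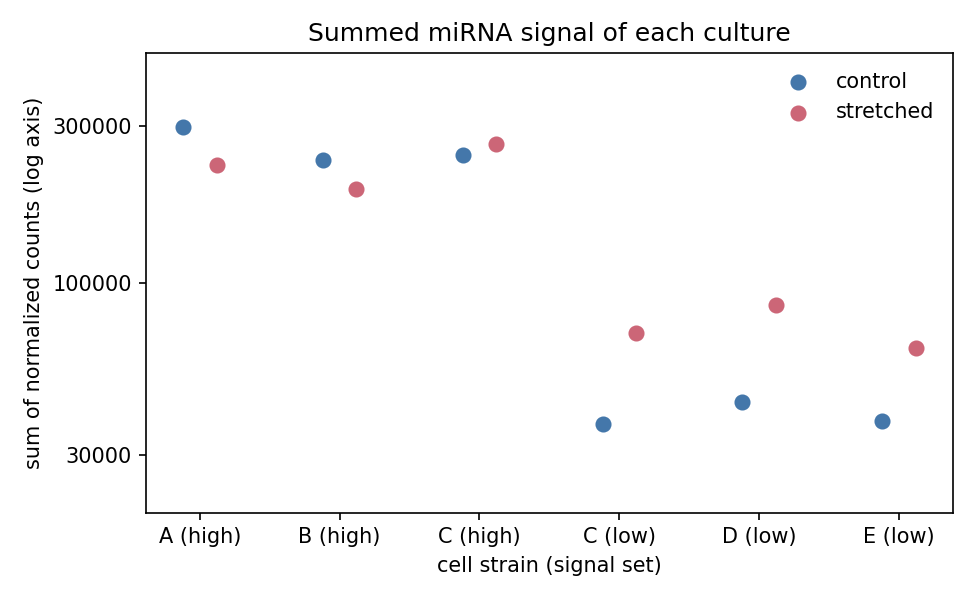
The sum of normalized counts over all 798 probes (log axis) for each culture, by strain and signal set, with control in blue and stretched in red. Each point is 1 culture. The 6 high-signal cultures lie at 193011 or above and the 6 low-signal cultures at 85629 or below.

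Control cells were dominated by a small number of miRNAs. miR-125b-5p took 17.4% ± 5.30 (SD, n = 5 strains) of the summed signal and let-7a-5p 13.9% ± 4.70. The probe for miR-4454 and miR-7975 came next by mean share, with 7.46% ± 5.42 (range 2.13% to 14.4%), and miR-29b-3p, a repressor of collagen mRNAs, with 7.22% ± 1.58. let-7b-5p made up 5.14% ± 1.16, miR-23a-3p 3.37% ± 1.11 and miR-100-5p 2.98% ± 1.79. miR-21-5p, a miRNA induced in fibrosis, made up 2.52% ± 1.24, let-7i-5p 2.18% ± 1.70 and the smooth muscle miRNA miR-145-5p 1.08% ± 0.503. These ranks depend on the signal set. Over both conditions, the mean count of the miR-4454 and miR-7975 probe was 8307 in the high-signal and 6074 in the low-signal cultures, that of let-7a-5p 40264 and 4276, of miR-29b-3p 18172 and 5983 and of let-7b-5p 12493 and 2465. miR-145-5p, at 2538 and 577.2, was not among the 10 highest mean counts of either set. The 10 named by control share together held 63.2% ± 7.73 in control and 64.8% ± 4.09 in stretched cells. With the share taken per culture and compared within strains, it was higher under stretch by 2.35 percentage points ± 3.58 (SD, n = 5 strains; exact permutation p = 0.354, two-sided), and the signal sets differed: it went from between 54.5% and 54.9% to between 59.8% and 61.3% in the 3 low-signal pairs, and changed by -2.10 to -0.253 points in the 3 high-signal pairs. These shares include the background of all probes, which weighs more in a low total. The totals of the low-signal pairs rose 1.67- to 1.97-fold under stretch, so the rise in share cannot be parted from the rise in total. Shares with background subtracted were not computed. The 9 let-7 family members together held 23.9% of the control signal.

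In the main setting miR-4286 was called as higher under stretch. Its normalized count was 90.0 ± 29.4 in control and 236.2 ± 117 in stretched cells (SD, n = 5 strains), a 2.53-fold rise (log2 change 1.34, SE 0.34, 95% interval 0.67 to 2.01, limma adjusted p = 0.0148). The main fit pooled the variance fully over miRNAs of like level (infinite prior degrees of freedom). Its SE, interval and p for a miRNA thus do not use that miRNA's own spread between strains. The log2 changes of miR-4286 ran from 0.58 in strain B to 2.06 in strain D. miR-4286 was higher under stretch in 5 of 5 strains, with an exact permutation p of 0.0208, the smallest the design allows, which 2 of the 163 miRNAs reached (smallest adjusted exact p 0.755). Its signal did not follow the total. Its mean count was 149.5 in the high-signal and 180.8 in the low-signal cultures (log2 ratio -0.11), while the median kept miRNA had a log2 ratio of 1.64. Whether its values reflect miRNA of the cells is thus not known. Among the 163 kept miRNAs miR-4286 was the only one past the threshold in limma (1 rose and 0 fell), while 20 had an unadjusted p under 0.05. The median miRNA had a log2 change of 0.31 on the deposited scale, so miR-4286 stood 1.03 above the median. The call was lost with top-100 scaling, which moved the median to -0.11 (miR-4286 log2 change 0.92, adjusted p = 0.0536). It was also lost without the strain block (adjusted p = 0.975), with all 12 cultures and the strain as a fixed block (0.841) or a random block (0.266), and without strain A, C or E (adjusted p = 0.164, 0.16 and 0.0682), and 3 of 48 splits of the cultures within strains, the real one included, gave at least 1 call.

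**Figure D2:**
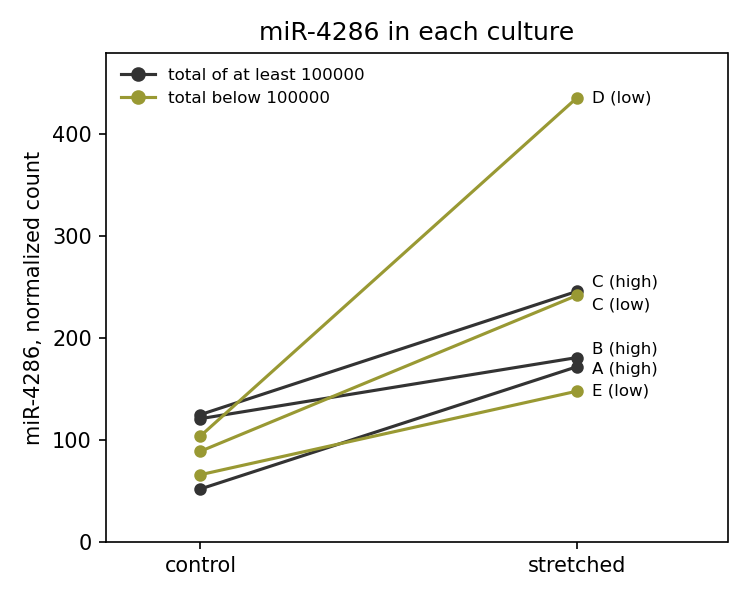
The normalized count of miR-4286 in the control and the stretched culture of each strain and signal set, with lines joining cultures of a strain within a signal set. Dark lines are the high-signal and light lines the low-signal cultures, and all 6 lines rise.

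Of the other miRNAs, 8 had a change of the same sign in all 5 strains without passing the threshold. Signs of some of the 163 miRNAs also agree in all 5 strains by chance. The number to be expected was not computed, so this count is not evidence of a response. miR-503-5p, a relative of the cell cycle regulators miR-15 and miR-16, had a log2 change of 0.89 (SE 0.29, limma adjusted p = 0.156). Its mean count was 17.8 ± 8.23 in control and 51.2 ± 68.8 in stretched cells, a mean set largely by strain A, whose log2 change was 2.54. miR-27a-3p had a log2 change of 0.59 (SE 0.28, adjusted p = 0.395), from 23.5 ± 6.36 to 37.5 ± 16.8. miR-574-3p had 0.65, miR-181a-5p 0.67, miR-185-5p 0.45, miR-574-5p 0.40 and miR-214-3p 0.34, with adjusted p from 0.42 to 0.52. miR-1290 was the one with a lower value under stretch in all strains (log2 change -0.48, 35.5 ± 10.6 against 24.2 ± 5.50). With strain C parted by signal set, miR-214-3p rose in 5 and fell in 1 of the 6 pairs. Relative to the median change of all miRNAs, miR-214-3p stood at 0.03 and miR-574-5p at 0.09. miR-574-5p turned sign with quantile normalization (-0.0526) and miR-214-3p with a pseudocount of 10 (-0.0027) and with all 12 cultures in the block (-0.0432).

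None of the 10 lists tested passed the threshold against the other miRNAs (camera, 0 with adjusted p under 0.05, 1 with unadjusted p under 0.05; 0 with an estimated correlation). Tested against no change in one direction, with fry, 0 lists passed (smallest unadjusted p 0.0854, for the miR-15/16 family). The fry test for change in either direction also passed 0 (smallest unadjusted p 0.083, for the fibrosis list). The miR-29 family, which represses collagens and other matrix mRNAs, had the smallest p in camera but not in fry (unadjusted p = 0.031 and 0.159): 3 of 3 members had a positive change, 0 passed the threshold over all miRNAs and 0 adjusted over the list alone (camera adjusted p = 0.31, unadjusted p = 0.261 with an estimated correlation). Relative to the median, miR-29a-3p stood at 0.70, miR-29b-3p at 0.36 and miR-29c-3p at 0.33. On the deposited scale the rise lay in the low-signal pairs, where the log2 changes of miR-29a-3p, miR-29b-3p and miR-29c-3p were 1.91, 1.35 and 1.51, against 0.07, -0.04 and -0.14 in the high-signal pairs. The median miRNA changed by 0.87 in the low-signal and -0.12 in the high-signal pairs. With top-100 scaling no member's difference between the sets passed (limma interaction, adjusted p = 0.103, 0.65 and 0.266). In the miR-23/27/24 clusters 5 of 5 members lay above the median, with 0 passing (camera adjusted p = 0.338); miR-27b-3p stood at 0.43, miR-24-3p at 0.30 and miR-23a-3p at 0.16. In the fibrosis list 5 of 7 lay above the median and 0 passed (adjusted p = 0.666); the probe for miR-199a-3p and miR-199b-3p stood at 0.79, miR-21-5p at 0.56, miR-199a-5p at 0.28 and miR-377-3p at 0.26.

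In the miR-15/16 family 4 of 5 members lay above the median, 0 passed over all miRNAs and 1, miR-503-5p, passed adjusted over the list alone (camera adjusted p = 0.537). miR-15a-5p stood at 0.42, miR-16-5p at 0.22 and miR-424-5p at 0.01. The miR-17-92 clusters had 6 of 9 above the median and 0 passing (adjusted p = 0.683), with miR-25-3p at 0.49, miR-19b-3p at 0.42, miR-93-5p at 0.41 and the miR-106a-5p and miR-17-5p probe at 0.20. The let-7 family had 4 of 9 above it and 0 passing (adjusted p = 0.917), with let-7i-5p at 0.35, let-7d-5p at 0.13, let-7g-5p at 0.06 and miR-98-5p at 0.04. The miR-30 family had 2 of 5 above it and 0 passing (adjusted p = 0.812), with miR-30a-5p at 0.38, miR-30d-5p at 0.13, miR-30e-5p at -0.02 and miR-30c-5p at -0.08. The senescence list had 2 of 3 above it and 0 passing (adjusted p = 0.683), with the p53 target miR-34a-5p at 0.29, miR-22-3p at 0.24 and miR-146a-5p at -0.11.

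The vascular flow list had 7 of 14 members above the median and 0 passing (camera adjusted p = 0.917); its mean stood at -0.0031 and miR-19a-3p at 0.10. The imprinted DLK1-DIO3 cluster had 12 of 23 above it and 0 passing (adjusted p = 0.812), with miR-136-5p at 0.47, miR-337-5p at 0.30 and miR-495-3p at 0.27. Of lists too short to test, the smooth muscle miRNAs miR-143-3p and miR-145-5p stood at 0.01 and -0.07, and miR-221-3p and miR-222-3p at -0.18 and 0.26. With quantile normalization let-7d-5p, let-7g-5p, miR-143-3p and miR-424-5p turned sign relative to the median.

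Markers of other cell types ranged from below the filter to a mean of 203.7 in control cells. The epithelial, striated muscle, miR-200, miR-183, C19MC and hypoxia lists had 0 kept members, and their highest members averaged 22.1 (miR-200a-3p), 21.3 (miR-133a-3p), 22.1 (miR-200a-3p), 20.7 (miR-183-5p), 27 (miR-520f-3p) and 23.9 (miR-210-3p). The endothelial miR-126-3p was 48.9 ± 40.8 in control and 51.8 ± 30.3 in stretched cells, and the blood miR-486-3p 30.3 ± 13.1 and 34 ± 31.9. The neuronal markers miR-137 (203.7 ± 259 and 179 ± 159) and miR-132-3p (100.2 ± 62.8 and 115.5 ± 36.8) were kept. The liver miR-122-5p was 160.5 ± 18.1 and 149.6 ± 43.0, and the pluripotent miR-302d-3p 41.7 ± 12.8 and 47.1 ± 14.6. The signal of miR-122-5p, miR-302d-3p and miR-486-3p did not follow the total. Their mean counts were 136.8, 39.5 and 25.8 in the high-signal and 171, 47.8 and 37.5 in the low-signal cultures. Whether these values reflect miRNA of the cells is thus not known. miR-126-3p, miR-137 and miR-132-3p were higher in the high-signal set. None of the kept markers passed the threshold in limma (smallest adjusted p 0.509), and housekeeping mRNA probes were not analysed here.

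The change under stretch differed between the signal sets. In the low-signal set, limma called 94 of 163 miRNAs, of which 94 rose and 0 fell, with a median log2 change of 0.87. In the high-signal set it called 0 (10 with an unadjusted p under 0.05), with a median of -0.12. An interaction term gave 87 miRNAs whose change was larger in the low-signal set and 0 whose change was smaller. The 87 include miR-1246, which lay at the floor of 1 in the low-signal cultures. Its log2 change was 0 there and -1.59 in the high-signal set, so its call is not a larger response in the low-signal set. With top-100 scaling the low-signal set gave 9 that rose and 33 that fell, the high-signal set gave 1 and 1, and the interaction gave 0 whose change was larger in the low-signal set and 2 whose change was smaller, neither of them among the 87. With quantile normalization both sets gave 0 calls (34 in the low-signal and 11 in the high-signal set with an unadjusted p under 0.05). The mean of the pair medians was higher by 0.96 in the low-signal set, with an exact permutation p of 0.1, the smallest that 3 pairs against 3 allow. miR-4286 had a log2 change of 1.55 in the low-signal set (adjusted p = 9.3e-05) and 1.08 in the high-signal set (adjusted p = 0.122). With top-100 scaling these were 0.51 (adjusted p = 0.0846) and 1.20 (adjusted p = 0.00625), so the set that held the call changed, and with quantile normalization 0.34 (adjusted p = 0.451) and 0.98 (adjusted p = 0.456).

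**Figure D3:**
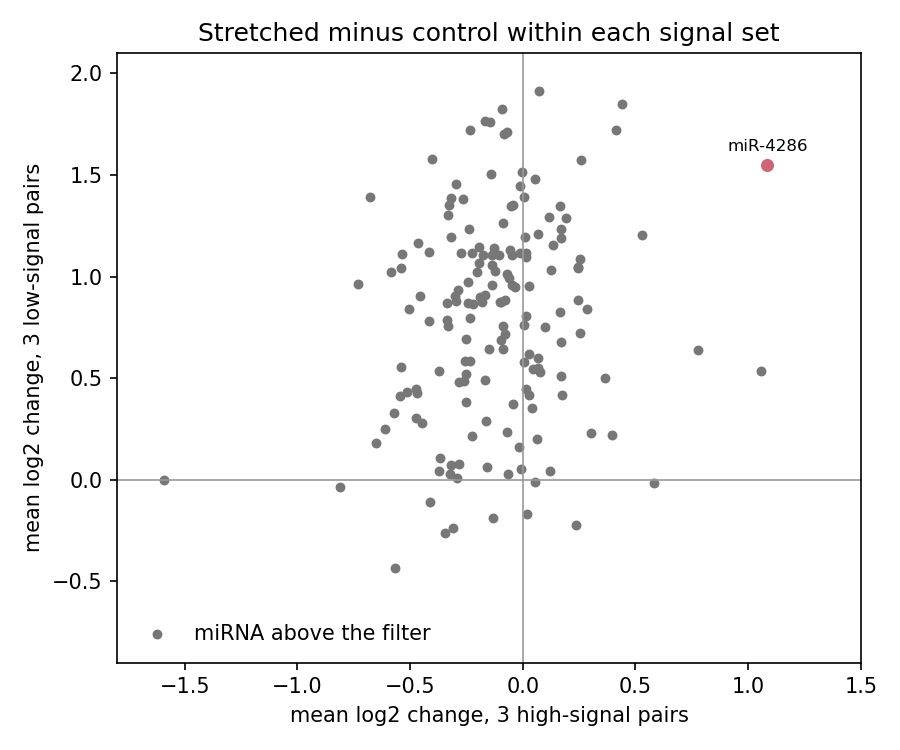
Mean log2 change (stretched minus control) of each of the 163 kept miRNAs in the 3 high-signal pairs (horizontal axis) and the 3 low-signal pairs (vertical axis), on the deposited scale. Each point is 1 miRNA; the median is -0.12 horizontally and 0.87 vertically, and miR-4286 (red) lies at 1.08 and 1.55.

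Strain accounted for 62.3% of the variance of the kept miRNAs and stretch for 3.46%, with 34.2% remaining. Relabelling the cultures within strains gave a median stretch share of 2.37% (exact permutation p = 0.438, one-sided). Without strain C the strain share was 88.7%. The cultures of strain C correlated with r of 0.94 or more within a signal set and 0.74 to 0.81 between the sets, across miRNAs, which are not independent replicates. The strain share cannot be parted from the signal set, since strains A and B lie in one set and D and E in the other. Cultures of different strains correlated with a median r of 0.912 within a signal set and 0.823 between sets, and the cultures of strain C with 0.775 between sets.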

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

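The tests of the signal sets, of strain C and of miR-4286 were chosen after the values had been seen, except the correlation with the ratio between sets and the counts of other splits.

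The change under stretch differed between the 3 low-signal and the 3 high-signal pairs for 87 miRNAs by an interaction term. The highest pair median in the high-signal set was 0.146 on the log2 scale and the lowest in the low-signal set 0.61, which restates the difference and does not decide whether strains share a response. With top-100 scaling the rising miRNAs in the low-signal pairs went from 94 to 9, with 33 that fell, and the interaction calls from 87 larger in the low-signal set to 0 larger and 2 smaller, but this scaling centres the change, so a technical difference in total signal and a real rise of total miRNA cannot be told apart by it. Whether the rise scales with each miRNA's ratio between the sets cannot be told apart from other trends, since the Spearman rho across miRNAs of 0.499 lay between the bounds of 0.5 and 0.2. Both remain open, since no measure of input RNA was used here.

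miR-4286 rose in all 6 pairs. It is itself a probe whose signal does not follow the total, with a mean count of 149.5 in the high-signal and 180.8 in the low-signal cultures. Unequal total signal as the whole cause is argued against by its log2 change of 1.085 in the high-signal pairs, where the median miRNA did not rise. A general rise of probes that do not follow miRNA content is argued against only in part by the 14 other probes whose signal differed by under 0.5 between sets, whose median log2 change was -0.0254. These are a mixed set. They include miR-127-3p and miR-370-3p of the DLK1-DIO3 cluster, whose level differs between strains. Others lie near background, such as miR-612 with means of 39.2 and 41.2, which mutes their change. Chance is not excluded for the count of 1 called miRNA: 3 of 48 splits of the cultures within strains gave as many, and the highest other gave 74. The splits with 74 and 33 calls put the culture with the higher total on the same side in 5 of 5 strains, against 3 of 5 in the real split, which points to total signal as a structure of the samples. The real count of called lists was 0, which every split reaches, so the 48 splits do not test it (highest other 2).

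The 4 cultures of strain C showed 2 profiles that follow the signal sets. A lower signal alone is argued against by the DLK1-DIO3 cluster, in which 21 of 23 members were higher in the 2 low-signal cultures than in the 2 high-signal cultures, while 7 of 140 other miRNAs were. The bound first set for this test was a median above 1, which the median of 0.911 missed; the count of members was used after that. A label that covers 2 strains may account for the profiles, since the 2 control cultures correlated with r = 0.742, within the 0.721 to 0.825 between controls of other strains of unlike signal set. The series' design text counts 6 cell lines, while the labels used here give 5. No other identity check was run, and a difference in passage or culture of 1 strain was not tested.

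Single values far from the rest of their group were found in 5 of 153 groups, where chance gives about 5%. In 1 stretched culture miR-503-5p had a log2 value of 7.451 (next 4.858), and in 1 strain its change was 2.544 (next 0.737). The change of miR-377-3p was 2.361 in 1 strain (next 0.305). miR-146a-5p had 7.14 in 1 control culture (next 4.755) and 7.011 in 1 stretched culture (next 4.858).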

How the results depend on the processing

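The tests within signal sets, with 6 pairs and with background subtracted were chosen after the data had been seen. The count of 1 called miRNA became 2 with a pseudocount of 10 (1 rose, 1 fell), and 0 without a filter, with top-100 scaling, with quantile normalization, without the strain block (no replicate block), and with 12 cultures and strain as a fixed or random replicate block. It ranged from 0 to 2 when 1 strain or 1 culture of strain C was left out. Pairing the cultures of strain C within their signal set, a pairing found from the data, gave 1 call, or 2 with top-100 scaling and 0 with quantile normalization. The high-signal set alone gave 0, 2 with top-100 scaling and 0 with quantile normalization, and the low-signal set alone gave 94, 42 (9 rose, 33 fell) and 0. Background subtraction, which took 14 off each value, gave 0 calls with either scaling. Unadjusted p under 0.05 numbered 20 in the main setting, 50 without a filter, 32 with top-100 scaling or quantile normalization, 1 without the block and 1 with 12 cultures in a fixed or random block, and 25 and 30 with background subtracted. More miRNAs were tested without a filter and fewer samples entered when some were left out; otherwise the cause was not tested. miR-4286 kept its sign relative to the median in every alternative run, from 0.34 to 1.21, and its adjusted p ranged from 9.3e-05 to 0.975. Its call was lost in 20 of 33 alternatives. Leaving out strain A, C or E or 3 of the 4 cultures of strain C in turn (adjusted p up to 0.332) was enough. The 20 include the exact permutation test, whose smallest adjusted p was 0.755. That test could pass only if many miRNAs reached its smallest p of 0.0208, and 2 did. Its loss thus does not weigh against miR-4286. The number of called lists stayed at 0 in the alternatives run, except that leaving out 1 culture of strain C gave 0 to 1; a blocked fit changed no list call. The share of variance by strain ranged from 48.7% to 88.7% when 1 strain was left out, and 88.7% without strain C; the stretch share did not pass in any alternative run. With the 6 pairs, chosen after the data had been seen, in place of the 5 strains, the pairs held 89.4% of the variance, stretch 3.46% and the rest 7.17% (exact permutation p = 0.156, or 0.0625 with top-100 scaling). The share of the 10 most abundant miRNAs was the same from the second deposited table. Without raw counts, the depth of a culture is known only as its sum of normalized counts; in the low-signal set most kept miRNAs lie nearer the background of 13 to 14, which limits how small a change can be measured there.

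Of the changes of single named miRNAs, given relative to the median, 1404 values kept their sign and side of the threshold, 43 passed it, 20 no longer did and 160 turned sign or met 0; those that turned had not been called, and why each turned was not tested. With a pseudocount of 10, the values were miR-214-3p -0.0027 and miR-30e-5p 0. With a mean of at least 100, the values were miR-574-5p -0.0563, let-7d-5p -0.0163, miR-98-5p -0.10, let-7g-5p -0.0863, miR-30d-5p -0.0154, miR-143-3p -0.13, miR-132-3p -0.0609 and miR-137 -0.0642. With quantile normalization, the values were miR-574-5p -0.0526, let-7d-5p -0.0495, let-7g-5p -0.11, miR-143-3p -0.11 and miR-424-5p -0.0027. With all 12 cultures and strain as a fixed or random replicate block, and with the 6 pairs as a block on either scaling, the values were miR-214-3p -0.0432 and miR-424-5p -0.0656. In the high-signal set alone, with or without top-100 scaling, the values were miR-29c-3p -0.0203, miR-93-5p -0.0236, let-7d-5p -0.0566, miR-98-5p -0.21, let-7g-5p -0.10, miR-30e-5p 0.20, miR-377-3p -0.21, miR-146a-5p 0.18, miR-15a-5p -0.11, miR-16-5p -0.17 and miR-126-3p 0.14. In the low-signal set alone, with or without top-100 scaling, the values were miR-503-5p -0.33, miR-27a-3p -0.23, miR-185-5p -0.0434, miR-214-3p -0.65, miR-574-5p -0.12, miR-30c-5p 0.0327, miR-145-5p 0.0653, miR-424-5p -0.89, miR-221-3p 0.15 and miR-302d-3p 0.17. With background subtracted, with or without top-100 scaling, the values were miR-214-3p -0.20, miR-23a-3p -0.0221, let-7d-5p -0.0204, let-7g-5p -0.0748, miR-143-3p -0.15, miR-146a-5p 0.15, miR-424-5p -0.31 and miR-126-3p 0.0183. With the 6 pairs as a block and quantile normalization, the values were miR-181a-5p -0.0124, miR-574-5p -0.0234, let-7d-5p -0.0425, let-7g-5p -0.0612, miR-143-3p -0.0269 and miR-424-5p -0.0617. In the high-signal set with quantile normalization, the values were miR-23a-3p -0.20, miR-98-5p -0.10, let-7g-5p -0.0834, miR-30e-5p 0.16, miR-377-3p -0.17, miR-146a-5p 0.18, miR-15a-5p -0.0864, miR-16-5p -0.17 and miR-126-3p 0.11. In the low-signal set with quantile normalization, the values were miR-181a-5p -0.24, miR-214-3p -0.23, miR-574-5p -0.20, let-7d-5p -0.0801, let-7g-5p -0.034, miR-30c-5p 0.10, miR-143-3p -0.16, miR-34a-5p -0.15, miR-424-5p -0.60, miR-222-3p 0, miR-132-3p -0.0132 and miR-302d-3p 0.31. Leaving out 1 strain or 1 culture of strain C gave, from lowest to highest, miR-27a-3p -0.0015 to 0.57, miR-214-3p -0.24 to 0.29, miR-30c-5p -0.15 to 0.0622, miR-424-5p -0.38 to 0.29, miR-574-5p 0 to 0.21, miR-145-5p -0.24 to 0.0699, miR-98-5p -0.21 to 0.32, let-7g-5p -0.17 to 0.31, miR-143-3p -0.17 to 0.11, miR-146a-5p -0.36 to 0.0302, miR-137 -0.0124 to 0.18, miR-377-3p -0.0972 to 0.61, let-7d-5p -0.0301 to 0.29, miR-30e-5p -0.11 to 0.0604, miR-126-3p -0.23 to 0.0425, miR-132-3p -0.0558 to 0.25, miR-136-5p -0.037 to 1.00, miR-495-3p -0.0708 to 0.64, miR-337-5p -0.0651 to 0.69, miR-16-5p -0.0366 to 0.50, miR-106a-5p and miR-17-5p (joint probe) 0 to 0.41, miR-19a-3p -0.0273 to 0.23 and miR-302d-3p -0.45 to 0.14.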

Other observations

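The tests reported here were chosen after the values had been seen. The examples were picked for their size. Among the cultures of strain C, miR-127-3p of the DLK1-DIO3 cluster averaged 41.5 in the high-signal and 263 in the low-signal cultures, and miR-136-5p 17 and 105. miR-376a-3p averaged 50 and 168, and miR-154-5p 8.0 and 26.5. The inflammation-linked miR-146a-5p went the other way, at 0.16 times its high-signal mean in the low-signal cultures (21.5), while the cultures of the other strains ranged from 16 to 28. miR-1246 averaged 118 and 1.0, with a range of 1 to 2111 in the other strains. Over all strains it averaged 471 in the high-signal cultures and 1, the floor of the values, in the low-signal cultures. Its contrast therefore follows the signal set and is not particular to strain C. These are values of 2 cultures each and were not tested.

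The level of the DLK1-DIO3 cluster differed between strains. Relative to the other miRNAs, its mean on the log2 scale ranged from -1.36 in strain E to 0.04 in strain A and was -0.75 in the low-signal cultures of strain C. The high-signal cultures of strain C lay outside this range at -3.54. This depends on the scale, since the other miRNAs are higher in the high-signal set: by its own mean log2 value the cluster stood at 8.05 in strain A, 7.16 in B, 6.01 in D and 4.70 in E, and at 5.34 in the low-signal and 4.58 in the high-signal cultures of strain C. Between control and stretched cultures of the same pair the value relative to the other miRNAs differed by -0.34 to 0.37.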
